A study of Homo sapiens with 8 samples.

How the data were processed

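Total RNA of human umbilical vein endothelial cells at passage 3 to 5 was measured in 8 samples, 4 exposed to vehicle and 4 to 10 µM acrolein, on 8 arrays of 1 Agilent human miRNA slide. Per the file headers, the authors scanned the slide in 1 colour and extracted it with Agilent Feature Extraction 9.5.3.1. The deposited scanner files hold, per spot, raw and background-subtracted signals as intensity, not scaled between arrays, with flags of 0 or 1 for outlier spots and for spots well above background. The deposited value table holds log2 values per probe: the authors centred each probe on its median over the 8 arrays and shifted the arrays against each other. How the arrays were shifted is not stated and was not recovered. The table has 1063 lines, 1044 of them for miRNA probes, and for the 16 of its probes that were above background on all 8 arrays its values followed log2 of the scanner signal with slopes of 0.858 to 1.05. Since only 20 human probes in it were above background on at least 4 arrays, the values were rebuilt from the scanner files.

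Each array had 12033 spots, 11080 of them for miRNA probes, with 5 to 40 spots per probe, and no miRNA spot was saturated. Spots with outlier flags and control spots were left out. The spots of a probe were averaged on the linear scale, and each array was scaled by the 75th percentile of its probe means over the 185 human probes detected on all 8 arrays (232 without acrolein array 4). A probe was detected where at least 50% of its spots were well above background, and a miRNA where at least 1 of its probes was. The probes of a miRNA were summed, values were floored at 8.55 (3.10 on the log2 scale), the median over arrays of the lowest scaled probe signal well above background, and log2 was taken. Human miRNAs detected on at least 4 arrays were tested, 147 over all 8 arrays and 145 without acrolein array 4. "At least" folds of a miRNA not detected on an array used the larger of its measured sum and the lowest detected probe signal of the array times its number of probes.

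Acrolein was compared with vehicle in limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Fixed lists with at least 3 tested members (13 of 18) were tested by camera with its preset correlation of 0.01, with an estimated correlation and by fry beside it. Detected miRNAs and total signal were compared by two-sided exact permutation tests of the group means. The arrays were not paired, a choice made beforehand. Once group means were removed, same-numbered arrays did not resemble each other (r of 0.01, −0.47, −0.13 and −0.18 for numbers 1 to 4). Acrolein array 4 weighs on that acrolein mean. Without acrolein array 4, r was −0.17, −0.74 and 0.07 for numbers 1 to 3. Positions came from the array files and genes around them from RefSeq gene symbols. The pipeline was tested on simulated data, 20 sets with the median residual SD of the comparison without acrolein array 4 (0.22, log2) for every miRNA. For that comparison it recovered 53 of 80 changes of 1.5-fold and 79 of 79 each of 2-fold and 4-fold changes. Only changed miRNAs that were tested were counted, and 17.3% of its calls were miRNAs that had not been changed. Changes were set only in the brighter tested miRNAs, so these rates do not cover dim ones such as miR-452. These rates do not describe the comparison over all 8 arrays, whose median residual SD was 0.48. The simulated noise was drawn separately for each miRNA. Shifts that many miRNAs of an array share were not simulated, so the rates may not hold for the real comparison without acrolein array 4 either.

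Groups of related miRNAs were fixed as lists: the let-7 family, the cluster from miR-17 to miR-92 and its paralogs, endothelial-enriched miRNAs, the miR-23-27-24 clusters, the miR-15/16 seed family, the miR-29 and miR-30 families, p53-responsive, NF-kB and inflammation, oxidative stress, shear-responsive and angiogenic and hypoxia-responsive miRNAs, the DLK1-DIO3 and C19MC clusters, a list named GC-rich, whose GC content was not measured, and miRNAs of blood, muscle, epithelium, and nerve and liver. The named miRNAs were, per comparison, up to 12 with the largest rise and 12 with the largest fall among those that passed, those with the smallest p until 20 were named, 12 miRNAs with known roles in endothelium or stress, the 2 members of each list with the smallest p (4 where the list passed) and the 5 brightest. These rules, the lists, the tests and the alternatives listed next were chosen before the data were examined. These alternatives were other backgrounds, scalings, probe summaries, detection rules, filters, floors, priors and array weights, the authors' table, a replicate block, exact tests and leaving out each array in turn. Leaving out acrolein array 4, leaving out both arrays numbered 4, list counts under settings other than quantile normalization, no scaling, no filter, the block, the estimated correlation and each array left out, and the covariate of viral probe signal were chosen after the data were seen. The comparison without acrolein array 4 used the same steps on the other 7 arrays.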

Results

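MicroRNA (miRNA) levels were measured in human umbilical vein endothelial cells (HUVEC, primary cells from the inner lining of the umbilical vein) after exposure to acrolein, a reactive aldehyde in cigarette smoke, or to vehicle. The cells were held in 0.1% serum, exposed to 10 µM acrolein or vehicle for 2 h and left to recover for 4 h. RNA from 4 vehicle and 4 acrolein samples was hybridised, 100 ng to an array, to Agilent arrays with probes for 470 human and 64 viral miRNAs. Between 131 and 166 human miRNAs (27.9% to 35.3%) were above background on an array, 95 of them on all 8 arrays, while 275 were above background on none. The number of arrays limits the precision, and since the labels do not say that the samples of a group were separate cultures, p-values measure only the spread between these samples, which may be technical. All arrays lay on 1 slide, vehicle in row 1 and acrolein in row 2, so slide row and group cannot be told apart.

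The first comparison asked which miRNAs differ between acrolein-exposed and vehicle-exposed endothelial cells. Over all 8 arrays no human miRNA passed the threshold: in limma 0 of 147 tested miRNAs were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.404. Of the 13 miRNAs with an unadjusted p under 0.05, 10 were lower and 3 higher after acrolein, a balance that moved with scaling to 9 lower and 8 higher with the median and 20 lower and 2 higher without scaling. The lowest p-values belonged to miR-513, with a log2 signal of 8.40 ± 0.15 in vehicle and 7.71 ± 0.13 after acrolein (SD, n = 4 each), and to miR-452, with 4.91 ± 0.25 and 4.20 ± 0.11. Log2 differences (acrolein minus vehicle) were −0.79 (SE 0.27) for miR-765, −0.78 (SE 0.24) for miR-622, −0.77 (SE 0.30) for miR-671 and −0.61 (SE 0.21) for miR-198, and miR-188 had log2 signals of 9.64 ± 0.46 in vehicle and 8.64 ± 0.60 after acrolein. On the other side miR-191* differed by 0.96 (SE 0.34) and miR-223, a miRNA of myeloid blood cells, by 0.95 (SE 0.35).

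Well-studied endothelial and stress-related miRNAs did not pass either, and many of them varied far more among the acrolein arrays than among the vehicle arrays. miR-126, which endothelial cells express from an intron of EGFL7 and which promotes VEGF signalling, had a log2 signal of 9.83 ± 0.36 in vehicle and 8.41 ± 3.55 after acrolein (SD, n = 4 each). The values were 10.64 ± 0.14 and 8.71 ± 3.74 for miR-222, 8.29 ± 0.14 and 6.94 ± 2.57 for its cluster partner miR-221, and 9.09 ± 0.21 and 7.46 ± 2.91 for miR-31. The log2 difference was −0.38 (SE 0.59) for miR-21, −0.43 (SE 0.60) for miR-155, an inflammation-linked miRNA, 0.32 (SE 0.46) for the hypoxia-induced miR-210 and 0.08 (SE 0.21) for the p53 target miR-34a. It was −0.07 (SE 0.25) for miR-10a, −0.28 (SE 0.25) for miR-126* and −0.09 (SE 0.55) for let-7b, and miR-146a was above background on none of the 8 arrays. Of the brightest miRNAs, miR-638 differed by −0.82 (SE 0.35), miR-370 by −0.63 (SE 0.22), miR-494 by −0.37 (SE 0.17) and miR-24 by −0.29 (SE 0.30). With array weights, which gave acrolein array 4 a weight of 0.0233, 38 miRNAs passed (21 higher, 17 lower). Exact permutation tests per miRNA gave 8 at an unadjusted p under 0.05 and 0 adjusted, a 0 set by the design, since at least 85 miRNAs would need the smallest possible p of 0.0286. The median log2 difference over the tested miRNAs was −0.18, and it ranged from −0.35 without scaling to −0.08 with scaling by the median.

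Acrolein array 4 stood apart from the other 7 arrays in its miRNA profile. All 7 epithelial miRNAs of the list fixed in advance, the miR-200 family with miR-141 and miR-429, miR-203 and miR-205, were above background on this array and on no other. The signal there was at least 48.1-fold higher for miR-141, 23.4-fold for miR-200c and 18.8-fold for miR-205 than the mean detection limit of the other arrays. Of the 13 endothelial-list miRNAs above background on all of the other 7 arrays, 9 were not above background there. The signal there was at least 113-fold lower for miR-222, 73.3-fold for miR-126, 37.3-fold for miR-31 and 22.3-fold for miR-221 than the mean of the other arrays. Across miRNAs, which are not independent replicates, log2 signals of this array had a Pearson r of 0.511 to 0.571 with the other 7 arrays, while the other 7 had 0.935 to 0.995 with each other. In all, 27 miRNAs were above background there alone, and 27 of the 122 found on all of the other 7 arrays were not above background there. These counts also depend on the detection limits. For miR-30b, miR-326, miR-34c, miR-423, miR-425-3p, miR-500, miR-660 and miR-769-5p the signal there was below the mean detection limit of the other arrays. No difference in level is shown for them, nor for miR-216 among those not above background there.

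**Figure D1:**
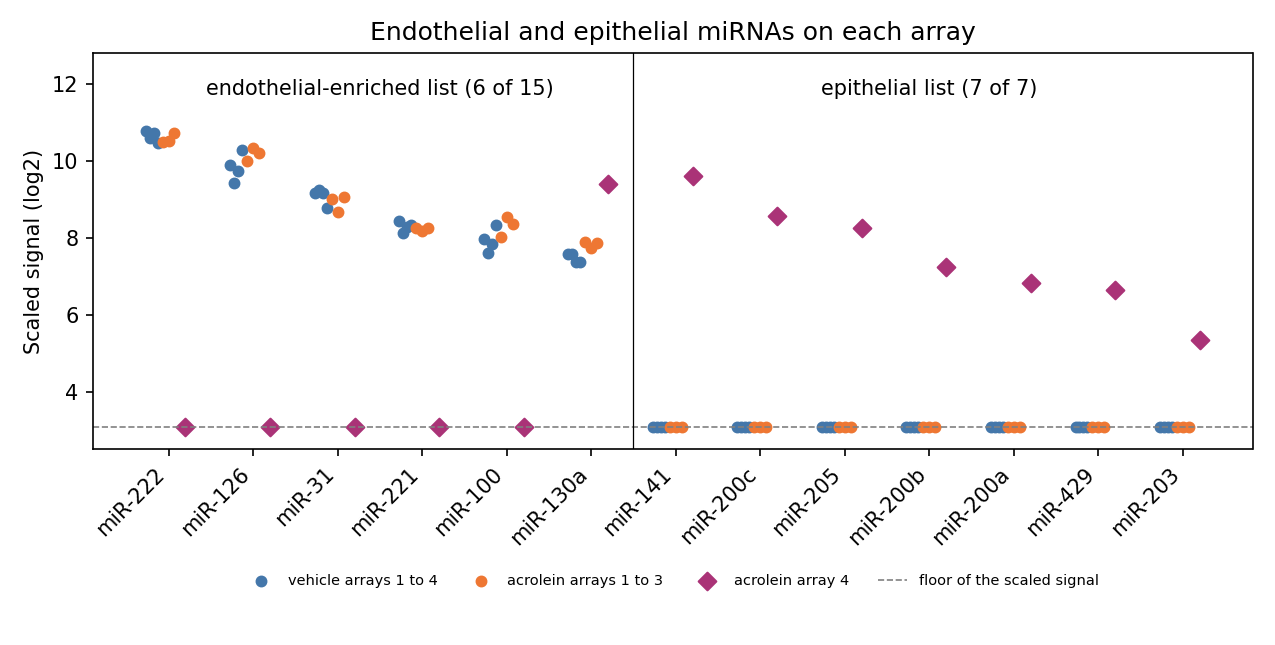
Log2 signal (scaled to the same 75th percentile, vertical axis) of endothelial-list and epithelial-list miRNAs on each of the 8 arrays (points), by group. On acrolein array 4 all 7 epithelial miRNAs are above background and miR-126, miR-222 and miR-31 are at the floor, while miR-130a is higher there (9.39) than on the other 7 arrays.

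The comparison was therefore repeated without acrolein array 4, a choice made after its values were seen, with 4 vehicle and 3 acrolein arrays. With the main settings 3 miRNAs passed, all lower after acrolein: miR-765 was 2.07-fold lower, miR-513 1.71-fold lower and miR-452 1.65-fold lower. The log2 signal of miR-765 went from 7.49 ± 0.28 (SD, n = 4) to 6.44 ± 0.19 (SD, n = 3), a difference of −1.05 (SE 0.17, limma adjusted p = 0.016). That of miR-513 went from 8.42 ± 0.15 to 7.64 ± 0.13, a difference of −0.78 (SE 0.14, limma adjusted p = 0.016), and that of miR-452 from 4.93 ± 0.23 to 4.21 ± 0.11, a difference of −0.72 (SE 0.15, limma adjusted p = 0.042). By the coordinates in the array files, whose genome build is not stated, probes for miR-765 lie on chromosome 1 at 155172572 to 155172591, for miR-513 on chromosome X at 146102744 to 146102763 and for miR-452 on chromosome X at 150878803 to 150878820. In the RefSeq annotation miR-452 lies within GABRE, a gene of a GABA receptor subunit.

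Of the 145 tested miRNAs 27 had an unadjusted p under 0.05, these 3 included, 16 of them lower and 11 higher after acrolein. This balance turned with scaling: 15 were lower and 19 higher with the 75th percentile of all human probes, 17 lower and 21 higher with quantile normalization, 11 lower and 33 higher with the median and 29 lower and 3 higher without scaling. The largest differences among those that did not pass were −1.81 (SE 0.44) for miR-565, 1.11 (SE 0.27) for miR-191* and 1.09 (SE 0.29) for miR-223. Lower values that did not pass belonged to miR-622 (−0.85), miR-188 (−0.81), miR-623 (−0.81), miR-663 (−0.77), miR-671 (−0.74), miR-638 (−0.73), miR-370 (−0.70), miR-198 (−0.69), miR-770-5p (−0.66), miR-575 (−0.57), miR-422b (−0.44) and miR-494 (−0.41), and higher values to miR-636 (0.83), let-7e (0.48) and miR-301 (0.46). Of the endothelial and stress-related miRNAs none passed once acrolein array 4 was left out. The largest difference of the set was 0.45 (SE 0.17, limma unadjusted p = 0.0289, adjusted p = 0.199) for let-7b, whose groups did not overlap. miR-126 differed by 0.29 (SE 0.20), miR-222 by −0.13 (SE 0.13), miR-221 by −0.13 (SE 0.13), miR-31 by −0.24 (SE 0.16), miR-21 by 0.20 (SE 0.18), miR-155 by 0.18 (SE 0.13), miR-210 by −0.25 (SE 0.14), miR-34a by 0.16 (SE 0.12), miR-126* by −0.21 (SE 0.19) and miR-10a by −0.06 (SE 0.22). The groups did not overlap for 19 miRNAs, where chance gives 5.71% of them or 8.29. That chance value is a mean, and miRNAs of the same arrays move together. Other splits of these arrays gave 27, 53 and 55, so the 19 do not show an effect of acrolein.

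The count and the direction of the miRNAs that passed depended on single arrays, on scaling and on the model. A replicate block gave 15 (3 higher, 12 lower), array weights 35 (16 higher, 19 lower) and the brightest probe or the mean of log2 probes 5 each (2 higher, 3 lower). The block leaves vehicle array 4 without a partner, so its differences rest on vehicle arrays 1 to 3 and acrolein arrays 1 to 3. It is therefore not separate from the fit below without vehicle array 4. Vehicle array 4 had an r of 0.981 to 0.989 with acrolein arrays 1 to 3 and of 0.957 to 0.978 with vehicle arrays 1 to 3. Without vehicle array 4 as well, 29 of 140 miRNAs passed (10 higher, 19 lower, all 3 above included), without acrolein array 1 15 passed, all lower, and without vehicle array 1, vehicle array 3 or acrolein array 3 none did. Scaling by the 75th percentile of all human probes gave 12 (3 higher, 9 lower), quantile normalization 11 (5 higher, 6 lower), no scaling 12 (all lower) and scaling by the median 0. The fit without a filter on dim miRNAs and that with a floor 4 times higher also gave 0, while miR-765, miR-513 and miR-452 were lower in every setting that gave them a value. Of these settings, arrays left out included, miR-765 passed in 15 of 23, miR-513 in 16 of 23 and miR-452 in 12 of 22. The log2 difference of miR-452 was as small as −0.063. The scalings above moved the median log2 difference over all tested miRNAs from −0.00 to between −0.15 (no scaling) and 0.14 (median).

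**Figure D2:**
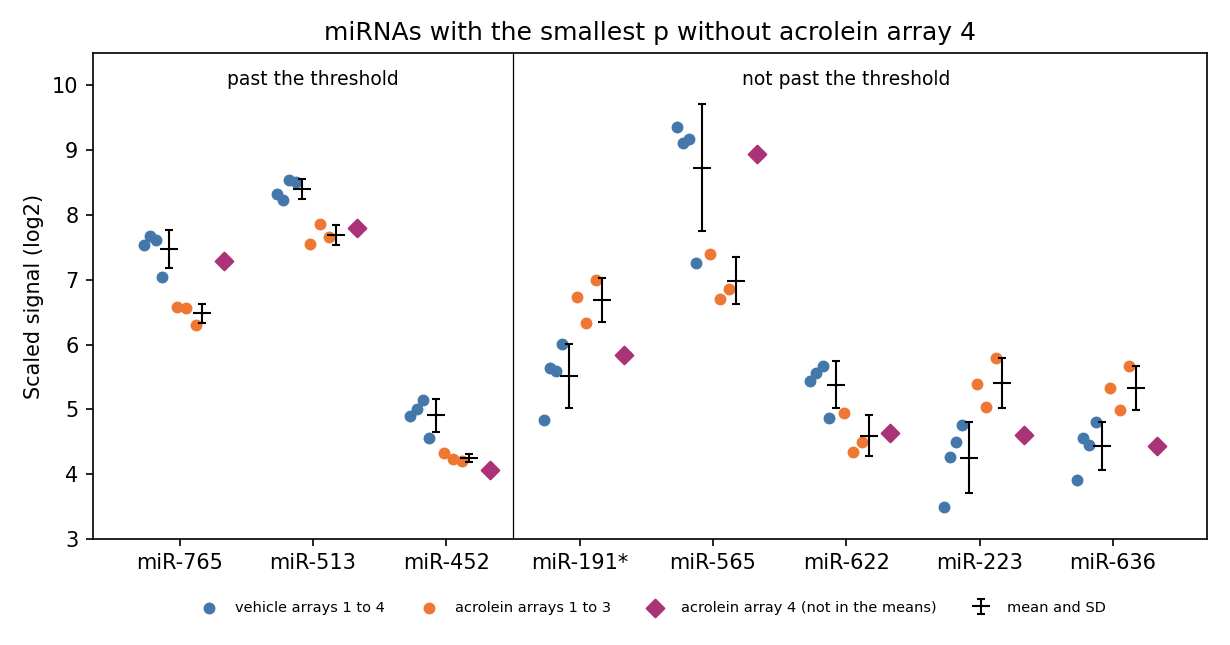
Log2 signal (vertical axis) of the miRNAs with the smallest p-values without acrolein array 4, per array (points) with group means and SD, on the scaling of all 8 arrays. Acrolein arrays 1 to 3 had lower values than the vehicle mean for miR-765, miR-513 and miR-452, the 3 miRNAs that passed.

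Lists of related miRNAs fixed in advance were compared next, first over all 8 arrays, where 3 of 13 passed in camera with its preset correlation and 0 with an estimated one. By fry 0 passed as well (smallest fry adjusted p = 0.268). The p53-responsive miRNAs rose relative to the other miRNAs: 5 of 5 tested members were higher after acrolein, among them miR-107 by 0.51, miR-16 by 0.56, miR-34b by 0.40 and miR-15a by 0.36 (log2; median 0.40, camera adjusted p = 0.025, adjusted p = 0.471 with an estimated correlation). The imprinted DLK1-DIO3 cluster fell: 16 of 18 tested members were lower, such as miR-370, miR-134 (−0.43) and miR-136 (−1.08), with a median of −0.36 (adjusted p = 0.037, adjusted p = 0.990 with an estimated correlation). Both calls moved with acrolein array 4: without it the adjusted p was 0.464 for each, with medians of 0.15 and −0.12. Without vehicle array 4 the adjusted p was 0.144 for each, and without acrolein array 1 it was 0.0585 for the DLK1-DIO3 cluster. Of 13 other settings of background, scaling, probes, filter, floor, outlier spots and block, the p53-responsive list missed the threshold in 7 (adjusted p up to 0.179) and the DLK1-DIO3 cluster in 5 (up to 0.225), while the GC-rich list below missed it in none. On acrolein array 4, 7 of 12 DLK1-DIO3 miRNAs that all of the other 7 arrays detected were not above background. No single miRNA of any list with at least 3 tested members passed when adjusted over the list alone in all 8 arrays.

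The list named GC-rich before the data were seen fell in both comparisons. Its GC content was not measured, since no sequences were at hand, and its members were neither all bright nor all miRNAs with high numbers. Over all 8 arrays 13 of 16 tested members were lower, with a median log2 difference of −0.57 (camera adjusted p = 0.000596, adjusted p = 0.471 with an estimated correlation). Without acrolein array 4 13 of 16 were lower, with a median of −0.63 (adjusted p = 0.000262, adjusted p = 0.786 with an estimated correlation): 2 of them, miR-765 and miR-513, passed over all miRNAs and 9 passed when adjusted over the list alone. Their direction was down under every scaling tried, with medians from −0.85 without scaling to −0.42 with quantile normalization. Viral miRNAs, which uninfected cells do not make, gave signals that moved with this list: of 8 viral miRNAs above background on at least 4 of the 7 arrays, 8 were lower on the acrolein arrays, with a median log2 difference of −0.80. With their mean signal as a covariate, 1 miRNA passed, miR-513 (−0.97, SE 0.20, adjusted p = 0.019), while miR-765 (−0.71, SE 0.22, adjusted p = 0.109) and miR-452 (−0.38, SE 0.20, adjusted p = 0.32) did not. The viral miRNAs were also tested in limma, adjusted over these 8 alone. hsv1-miR-H1 (−1.36), hcmv-miR-US4 (−1.33), ebv-miR-BART13 (−1.27) and ebv-miR-BART7 (−0.94) passed (limma adjusted p of 0.0018, 0.0018, 0.0020 and 0.020). The other viral miRNAs did not. A call on these arrays can thus arise without a human miRNA.

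**Figure D3:**
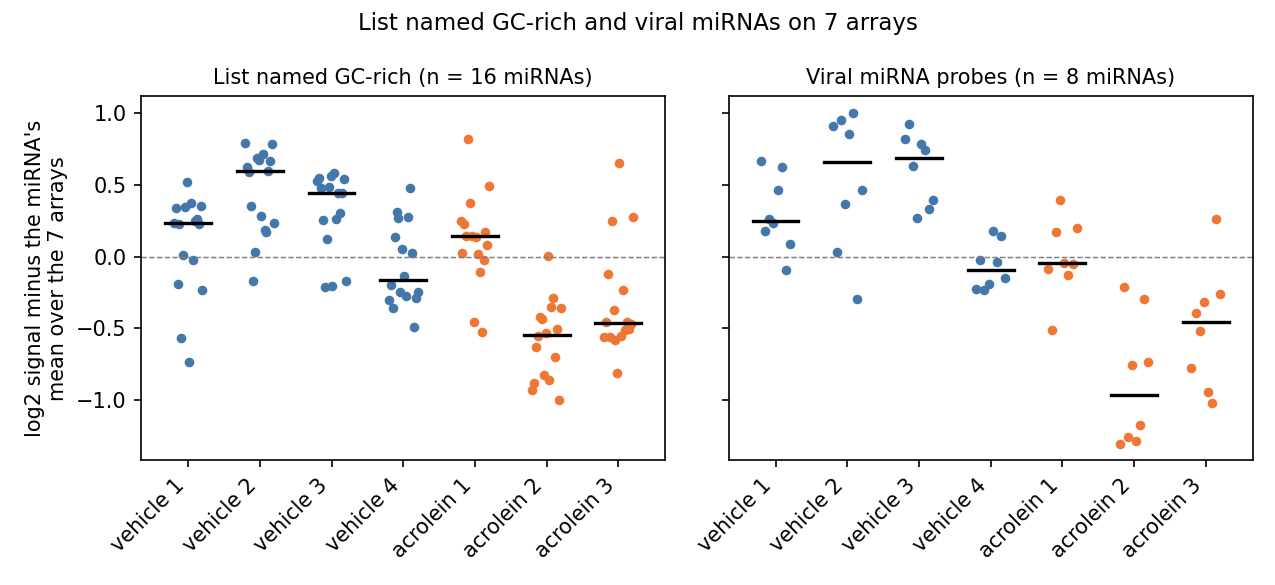
Log2 signal of each miRNA minus its mean over the 7 arrays (vertical axis) for the 16 tested miRNAs of the GC-rich list and the 8 viral miRNAs on each array without acrolein array 4 (points, with the median as a bar). On the acrolein arrays 13 of the 16 miRNAs of the list were lower, and the median log2 difference over all 16 was −0.63. All 8 viral miRNAs were lower, with a median of −0.80.

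The let-7 family, which represses RAS and other growth-related messages, rose relative to the other miRNAs without acrolein array 4, with 7 of 8 tested members higher: let-7e by 0.48, let-7b by 0.45, let-7d by 0.38 and let-7a by 0.34. The median was 0.32 (camera adjusted p = 0.026, adjusted p = 0.786 with an estimated correlation), and no member passed alone. All scalings kept the median above 0, but the adjusted p was 0.0559 with scaling by the 75th percentile of all human probes, 0.0559 with scaling by the median, 0.150 with quantile normalization, 0.0531 without scaling and 0.225 without the filter on dim miRNAs. It was 0.077 without vehicle array 2, 0.0584 without vehicle array 3 and 0.228 without acrolein array 2. The direction did not hold with the mean viral signal as a covariate. In that fit let-7e differed by 0.04, and all other tested members were below 0, from −0.04 for let-7b to −0.40 for let-7f. None of them passed, and camera was not run with the covariate. With acrolein array 4 included, 4 members were higher and 4 lower, and let-7g and let-7i, which the other arrays all detected, were not above background on that array. Of the 13 lists 0 passed with an estimated correlation or with fry without acrolein array 4.

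The other lists did not pass without acrolein array 4 with the main settings. The cluster from miR-17 to miR-92 and its paralogs, which promote proliferation, had 11 of 12 members higher, such as miR-20a (0.33) and miR-106a (0.31), with an adjusted p of 0.059. It passed in 5 of the 13 other settings, among them quantile normalization (adjusted p = 0.0116) and scaling by the median (0.0278), and without vehicle array 1 (0.0382), and its adjusted p over these settings ranged from 0.00553 to 0.222. Of the endothelial list 7 members were higher, such as miR-100 (0.30) and miR-130a (0.30), and 7 lower, such as miR-503 (−0.26), where over all 8 arrays 12 of 14 were lower with a median of −0.53 (adjusted p = 0.628, but 0.00184 without the filter on dim miRNAs). The miR-23-27-24 clusters had 5 of 5 lower, such as miR-27a (−0.48) and miR-27b (−0.21), and the miR-15/16 seed family had 4 of 5 higher, such as miR-15b (0.36) and miR-195 (0.35). The miR-29 and miR-30 families had 2 higher and 3 lower, such as miR-29a (0.15) and miR-30a-5p (−0.15). Of the NF-kB and inflammation list 5 were higher and 4 lower, with miR-125a at 0.36, and 1, miR-223, passed when adjusted over the list alone. The oxidative stress list, whose miR-200 members were above background on acrolein array 4 alone, had 4 higher and 2 lower. The shear-responsive and angiogenic list had 7 higher and 9 lower and the hypoxia-responsive list 3 higher and 4 lower, among them miR-103 (0.17) and miR-24 (−0.12). Camera gave a direction opposite to the sign of the median and of the mean for the let-7, miR-17 to miR-92, miR-29 and miR-30, NF-kB, oxidative stress and shear-responsive lists over all 8 arrays, and without acrolein array 4 for the hypoxia-responsive list, opposite to the median for the endothelial list and to the mean for the oxidative stress list. Of the other lists, the blood cell list had 1 tested member, miR-223, and the C19MC, muscle, epithelial and neural and liver lists had 0.

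The last comparisons asked whether acrolein changed the number of miRNAs above background or the total miRNA signal. Neither difference passed. Vehicle arrays had 142.5 ± 15.9 human miRNAs above background and acrolein arrays 148 ± 6.58 (SD, n = 4 each; exact permutation p = 0.571, two-sided). The difference of 5.5 turned to −2.75 by the flag for positive and significant spots and grew to 13.3 without vehicle array 4. The log2 total signal before scaling was 15.03 ± 0.18 in vehicle and 14.69 ± 0.20 after acrolein (SD, n = 4 each), a difference of −0.34 (exact permutation p = 0.0857, where 0.0286 is the smallest p that 4 against 4 arrays allow). Without acrolein array 2 the difference was −0.43 (exact permutation p = 0.0286), and without acrolein array 4 it was −0.33 (exact permutation p = 0.143). It shrank to −0.17 without the 5 brightest miRNAs (exact permutation p = 0.343) and to −0.11 with normexp background (exact permutation p = 0.0857). Without acrolein array 4, miR-623 was the only miRNA above background on all 4 vehicle arrays and none of the acrolein arrays. Its log2 signals overlapped all the same, with 4.52 on acrolein array 1 and 4.15 on vehicle array 4. The lowest detected probe signal also differed between arrays.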

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

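The tests of the 2 patterns weighed here, a miRNA profile apart and the fall of the GC-rich list, were chosen after the result was seen, while the counts over other splits were planned for all 8 arrays, and those over fewer arrays rest on a choice of arrays made after the data were seen.

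Of the 8 arrays, 1 did not match its group's labels: it had a miRNA profile apart from the other 7. RNA of another cell type mixed into endothelial RNA is argued against, since 9 of the 13 endothelial-list miRNAs that all of the other 7 arrays detected were not above background there, where a mixture would keep the abundant miR-126 and miR-222 in view. A response shared by the acrolein arrays is argued against too, since 0 of 7 epithelial-list miRNAs were above background on any of the other 3 acrolein arrays. That is part of the pattern itself, a profile found on 1 array, and so no separate test. A response to acrolein in this sample alone was not tested. RNA of another source than the label says stays open and may be epithelial: 7 of 7 epithelial-list miRNAs were above background there alone, with log2 signals of 9.60 for miR-141 and 8.56 for miR-200c. None of the 7 was detected on the other arrays, and 5 of them also stand in the oxidative stress list.

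The GC-rich list was lower on the acrolein arrays without acrolein array 4 (median log2 difference −0.63 over 16 members). A signal not specific to a human miRNA may account for it: the 8 detected viral miRNAs had a median of −0.80. With their mean signal as a covariate, miR-513 (−0.97), miR-765 (−0.71), miR-494 (−0.29), miR-198 (−0.12) and miR-575 (−0.10) stayed lower. The other tested members, 3 of which were higher without it, were then above 0, up to 0.82 for miR-625. The viral signal itself went with the groups, so this fit cannot separate it from acrolein. A difference between arrays unrelated to acrolein stays open as well, since vehicle array 4 differed from the mean of vehicle arrays 1 to 3 by a median of −0.45 over the same members. It lay below each of those arrays for 11 of the 16. The viral miRNAs were lower on vehicle array 4 too, by a median of −0.50, so both explanations may rest on the same shift. Acrolein exposure cannot be told apart from these: the groups did not overlap for 4 of the 16 members, and slide row follows the groups. No test here ranks these explanations.

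Splits of the arrays were counted with the main settings only. Chance cannot be excluded for the lists over all 8 arrays or for the miRNAs and lists over 7. Over all 8 arrays 14 of 35 splits gave as many lists (3 in the real split, at most 6 in another). For miRNAs the real split gave 0 there, so that 35 of 35 splits had to give as many (at most 1 in another) and the count tests nothing. Without acrolein array 4, 3 of 35 splits gave as many miRNAs (3 in the real split, at most 40 in another) and 15 of 35 as many lists (2 and 3). The split with 40 set vehicle arrays 1 to 3 apart from vehicle array 4 and acrolein arrays 1 to 3. Another, with 37, set vehicle array 4 and acrolein arrays 2 and 3 apart from vehicle arrays 1 to 3 and acrolein array 1. Both point to a structure of the samples that differs from the groups in vehicle array 4 and, in the split with 37, also in acrolein array 1. Without both arrays numbered 4 the real split gave 29 miRNAs, 1 of 10 splits gave as many and the highest other gave 0, but 10 splits are too few for a share under 0.05.

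The spread within groups was tested for the named miRNAs, the human and the viral miRNAs detected and the total signal. In 26 of 126 such groups, all of named miRNAs, 1 array lay far from the other 3 of its group, measured as its gap to the nearest of them as a share of the range of the group; chance gives about 1 in 20, or 6.3. Acrolein array 4 was the highest for miR-29c (0.992), miR-210 (0.911), miR-16 (0.910), miR-130a (0.905), miR-301 (0.877), miR-103 (0.876), miR-106b (0.859) and miR-23b (0.854). It was the lowest for miR-221 (0.986), miR-222 (0.970), miR-29a (0.970), let-7i (0.959), miR-126 (0.954), miR-31 (0.937), miR-155 (0.922), miR-100 (0.904), miR-20a (0.903), miR-106a (0.893), miR-195 (0.887), miR-21 (0.886) and miR-136 (0.837). Vehicle array 4 was the highest for miR-125a (0.833) and the lowest for miR-565 (0.886), miR-770-5p (0.886) and miR-210 (0.836). Acrolein array 1 was the highest of its group for miR-575 (0.854).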

How the results depend on the processing

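Leaving out acrolein array 4, both arrays numbered 4, or vehicle array 4 as well, the viral covariate, and list counts under settings other than quantile normalization, no scaling, no filter, the block, the estimated correlation and each array left out, were chosen after the data were seen; the other alternatives were planned. Of 61 named miRNAs 60 were tested, 20 of them changed sign under some alternative, and 12 of the 58 reversals came without acrolein array 4 and 12 with array weights, which lower its part; miR-765, miR-513 and miR-452 were lower in every alternative run without that array that gave them a value, which the deposited log2 values did not. Signal over background limits the rest: 275 of 470 miRNAs were above background on no array. A slide block was not run, since there is 1 slide, and array weights did not reach their convergence tolerance; camera uses neither these nor an intensity trend, so lists were not rerun with them. Except where fewer arrays were fitted, the cause was not tested.

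Over all 8 arrays (0 miRNAs in the report) a floor 4 times higher gave 1 (1 lower), array weights 38 (21 higher, 17 lower), both arrays numbered 4 left out 29 (10 higher, 19 lower) and leaving out each array 0 to 3 (higher 0 to 0, lower 0 to 3). The replicate block gave 0. Lists (3) numbered 0 with an estimated correlation, 2 with quantile normalization, which ended the p53-responsive call, 1 to 3 without each array and 1, the GC-rich list, with normexp background, the brightest probe, the mean of log2 probes, detection on all arrays and a floor 4 times higher; without a filter they numbered 3, with the endothelial list in place of the p53-responsive one. Without acrolein array 4 (3, all lower) the replicate block gave 15 (3 higher, 12 lower), the 75th percentile of all human probes 12 (3, 9), median scaling 0 (0, 0), quantile normalization 11 (5, 6), no scaling 12 (0, 12), the brightest probe 5 (2, 3), the mean of log2 probes 5 (2, 3), no filter 0, a floor 4 times higher 0, array weights 35 (16, 19), the exact permutation test 0 (fixed by its smallest p of 0.0286), the deposited log2 values 0 (20 probes, none for these 3 miRNAs), the viral covariate 1 (0, 1), and each further array left out 0 to 29 (0 to 10 higher, 0 to 19 lower). The block there leaves vehicle array 4 without a partner, so that array adds nothing to its differences. Lists (2) numbered 1 with the 75th percentile of all human probes, 1 without scaling, 1 without a filter, 0 with an estimated correlation and 1 to 3 without each array. The difference in detected miRNAs was −2.75 by the flag for positive and significant spots and 1.67 to 13.3 without each array; that in log2 total signal was −0.43 to −0.27 without each array, −0.17 without the 5 brightest miRNAs and −0.11 with normexp background.

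Log2 differences that changed sign were, with normexp background, miR-623 0.037, miR-126* 0.031, miR-10a 0.063, let-7b 0.057, miR-770-5p 0.000748, miR-106a 0.013 and miR-20a 0.013. With the 75th percentile of all human probes they were miR-106a 0.037 and miR-20a 0.041, and with median scaling miR-10a 0.035, let-7b 0.015, miR-106a 0.074 and miR-20a 0.078. With quantile normalization they were miR-21 0.047, miR-34a −0.043, miR-10a 0.0103, miR-106a 0.00302 and miR-20a 0.11, and without scaling miR-34a −0.0901, let-7d −0.15 and miR-195 −0.046. With array weights they were miR-126 0.38, miR-21 0.30, miR-210 −0.21, miR-155 0.27, miR-10a 0.095, let-7b 0.53, let-7i 0.11, miR-106a 0.39, miR-20a 0.44, miR-100 0.40, miR-27b −0.068 and miR-29a 0.22, and with outlier spots kept let-7d −0.000336. Without each array in turn the ranges were miR-126 −2.05 to 0.29, miR-21 −0.65 to 0.20, miR-210 −0.25 to 0.49, miR-155 −0.71 to 0.18, miR-34a −0.00356 to 0.16, miR-10a −0.23 to 0.10, let-7b −0.41 to 0.45, miR-23b −0.00952 to 0.77, miR-15a −0.00021 to 0.61, let-7d −0.19 to 0.38, miR-106a −0.21 to 0.31, miR-20a −0.20 to 0.33, miR-100 −1.43 to 0.30, miR-27b −0.21 to 0.67, miR-195 −0.046 to 0.35 and miR-29a −1.07 to 0.15.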

Other observations

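The miRNAs named in the next sentences were chosen after their values were seen, and the test of neighbouring miRNAs was planned before its result was seen. Beyond the epithelial list, acrolein array 4 differed in other tissue-restricted miRNAs. Its signal was at least 63.3-fold higher than the mean detection limit of the other 7 arrays for miR-449, a miRNA of ciliated epithelium, 6.73-fold for miR-449b, 5.04-fold for miR-149, 4.73-fold for miR-375, a miRNA of pancreatic islets and other epithelia, and 3.29-fold for miR-196a, encoded in the HOX clusters. Among miRNAs not above background there, the signal was at least 29.9-fold lower than the mean of the other arrays for miR-125b, 19.8-fold for miR-100, 14.5-fold for let-7i, 6.89-fold for miR-214 and 5.84-fold for miR-127, a member of the DLK1-DIO3 cluster.

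Without both arrays numbered 4, 3 vehicle and 3 acrolein arrays remained and 29 of 140 miRNAs passed in limma. The changes included a fall of miR-565 (log2 difference −2.28) and of miR-765 (−1.18) and a rise of miR-191* (1.28) and miR-223 (1.27). Vehicle array 4, left out here after its values were seen, was the lowest vehicle array for miR-565. Its r was 0.981 to 0.989 with acrolein arrays 1 to 3 and 0.957 to 0.978 with vehicle arrays 1 to 3. Leaving it out by itself sets the groups further apart, so the 29 are no separate support for an effect of acrolein. With vehicle array 4 kept, miR-565, miR-191* and miR-223 did not pass (limma adjusted p of 0.067, 0.067 and 0.076). With it kept and the viral covariate added, miR-565 differed by −0.48 (limma adjusted p = 0.51).

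Neighbouring miRNAs that share a primary transcript may change together. Over 84 pairs of tested miRNAs within 10 kb of each other, the median difference between their log2 changes without acrolein array 4 was 0.18, against 0.31 in the median of 10000 permutations of the changes among the miRNAs (one-sided permutation p = 0.002). The permutations drew from all 145 miRNAs with a position, of which 68 are in pairs. Some of the largest changes, such as those of miR-565, miR-223 and miR-765, are in no pair. The small p may come from that alone, so the test cannot show that neighbours change together. Of these pairs 54 of 84 had the same sign, such as miR-221 and miR-222 (−0.13 and −0.13) and let-7e and miR-125a (0.48 and 0.36), while miR-99b, next to miR-125a, was at −0.26. A shared probe signal between similar sequences was not tested, so the hypothesis stays open.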
